A study of Mus musculus with 2 samples.

How the data were processed

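Kidney leukocytes of NZB/W F1 mice were isolated by enzymatic digestion of minced kidney, a density gradient and cell sorting, and sequenced as 2 single-cell libraries of 5′ gene expression. The isotype control library pooled 2 mice and the anti-NKp46 library 3 mice. The deposited matrices hold counts, per the file headers whole numbers: raw UMI counts per gene and barcode, 1 matrix per library, for barcodes already called as cells. The deposited features and barcodes files hold other values, namely gene IDs with symbols and cell barcodes. Per the labels the authors used Cell Ranger 5.0.0 and the mouse genome build mm10, and no annotation release is stated in the sources used here. No map from cells to mice was used, so each group is 1 sample.

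Cells with at least 300 genes and at most 10% mitochondrial UMIs were taken, which were 11259 of 11356 barcodes in the isotype control library and 13018 of 13104 in the anti-NKp46 library. Scrublet was run per library with an expected rate of 0.05. Its automatic threshold called 0 doublets in both libraries, so a score threshold of 0.15 was set by hand after the scores had been seen. It removed 567 cells (5.04%) and 785 cells (6.03%), and left 10692 cells with a median of 3276 UMIs and 12233 cells with a median of 2298 UMIs. Both libraries were clustered together without integration (Leiden, resolution 1.2, 30 principal components of 3000 variable genes, 15 neighbours). The variable genes left out Ncr1, antigen receptor segments, mitochondrial, ribosomal protein and haemoglobin genes, and the members of the interferon, interferon gamma, dissociation stress and proliferation lists.

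Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 markers in at least 20% of the cells and at least 2-fold above all other cells. Clusters stayed unnamed when both libraries' median UMI counts were under 33.3% of the library's own median, or when a second lineage reached 15% of its highest cluster level. The pair of T and NK lineages was exempt from the 15% rule. Cluster 5, with its second lineage at 0.191 of that level, was therefore named NK/ILC1. NK and ILC1 clusters were divided again into 8 sub-clusters, and sub-clusters with Trac at 40% or more of the T-like level were kept apart. The doublet score, the 15% rule and the 40% rule were chosen after seeing the data. Of 30 clusters 21 were named and 9 were not.

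Raw counts were summed per library and class and given as CPM of the class total with exact Poisson 95% intervals. Ratios have exact conditional binomial 95% intervals, and shares have exact (Clopper-Pearson) 95% binomial intervals. All of them cover counting error only. With 1 library per group no test was made, and ratios describe these 2 libraries. For 26 gene lists fixed before the data were examined, the median log2 ratio (anti-NKp46 over isotype control, 0.5 count added to each sum) was taken over members with at least 20 UMIs in the class and set against 10000 random lists matched on expression. A list needed at least 5 such members, and members at least 1.5-fold apart were counted as a description of size. Shares of cells with a UMI were also taken after thinning each cell to 1000 UMIs.

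The genes named were fixed genes for each main class, up to 4 members of each list with the largest ratio among those with at least 50 UMIs, and the 10 highest and 10 lowest ratios in each main class (4 and 4 in other classes with at least 100 cells in each library). The last group needed at least 50 CPM in 1 library, at least 100 UMIs, and a level of at least 20% of the gene's highest class, as a guard against free RNA. Ratios within single monocyte clusters, and those of Rbm3, Cirbp and the heat-shock genes across classes, were chosen after their values had been seen. Positions came from the GENCODE vM21 annotation of GRCm38, in which 32235 of 32285 gene IDs were found.

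The alternatives were no cell filter, a stricter one (at least 800 genes, at most 5% mitochondrial UMIs), doublets kept, resolutions 0.6 and 2.0, each library clustered alone, all variable genes, a denominator without NK/ILC1-like cells, median-of-ratios scaling, a total without abundant gene families, the mean of per-cell CPM, thinned cells, and list members with at least 100 UMIs or with no minimum. A doublet score of 0.10, leaving out cells with 3 or more UMIs of another lineage, leaving out the NK/ILC1-like sub-cluster led by macrophage genes, and equal cluster weights were added after seeing the data, as was the use of the share settings for T subsets, dendritic cells, group 2 innate lymphoid cells and tubule cells. The steps were tested on simulated data, with 200 of 6319 genes changed in sums of 1000000 UMIs. The ratio lay on the right side for 100% of the genes changed 2-fold and 4-fold, and the interval held the true value for 96% and 95% of them and for 95.7% of 6119 unchanged genes. Of 20 unchanged lists, 19 lay between percentiles 2.5 and 97.5, and a list of 20 genes raised 1.5-fold lay at percentile 100. The simulated counts were independent Poisson draws, which the intervals assume, so coverage near 95% was built in. The simulation does not check intervals where UMIs gather in single cells, or percentiles where list genes vary together. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.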

Results

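Leukocytes from the kidneys of NZB/W F1 mice, a hybrid strain that develops a lupus-like immune complex nephritis, were profiled by droplet single-cell RNA sequencing of 5′ transcript ends. The first library came from 2 nephritic mice given poly(I:C), a synthetic double-stranded RNA that induces type I interferon, together with an isotype control antibody. The other came from 3 mice given an antibody that blocks NKp46, the activating receptor encoded by Ncr1 on natural killer (NK) cells and group 1 innate lymphoid cells (ILC1). The labels name poly(I:C) for the control mice and do not say whether the mice given the blocking antibody also received it. The animals of a group were pooled, so each group was 1 library and no spread between animals could be measured. All intervals given here are exact 95% intervals of counting error alone, and no test between the groups was made.

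The isotype control library held 11356 barcodes and 55016697 UMIs, with a median of 3359 UMIs and 1516 genes per barcode. The anti-NKp46 library was shallower per cell, with 13104 barcodes, 44308846 UMIs and medians of 2382 UMIs and 1147 genes. After filtering, 10692 and 12233 cells were kept, and they formed 30 clusters, of which 21 could be named from markers.

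The first question was whether blocking NKp46 went with another composition of kidney leukocytes. Monocyte-like cells, the circulating precursors of many tissue macrophages, made up 23.7% (22.9% to 24.6%) of cells in the isotype control library and 14.7% (14.1% to 15.3%) in the anti-NKp46 library, a difference of -9.03 percentage points, which was -4.96 at the coarser clustering resolution. Their clusters went apart as shares of all kept cells. Cluster 8, led by patrolling monocyte genes, was higher in the anti-NKp46 library, at 4.29% against 6.51%. Cluster 10 was lower, at 13.2% against 6.25%, and so was cluster 16, at 6.22% against 1.95%. B-like cells were higher with the blocking antibody, at 7.44% (6.95% to 7.95%) against 14.6% (13.9% to 15.2%). T-like cells made up 31.7% (30.8% to 32.6%) against 37.9% (37.0% to 38.7%). Antibody-secreting plasma cells were lower with the blocking antibody, 4.35% (3.97% to 4.75%) against 2.21% (1.95% to 2.48%), as were neutrophil-like cells, 2.79% (2.48% to 3.12%) against 1.57% (1.36% to 1.81%). Macrophage-like cells differed less, 7.38% (6.89% to 7.89%) against 6.0% (5.59% to 6.44%). The T-like difference of 6.17 percentage points came down to 1.36 when cells with under 800 genes or over 5% mitochondrial UMIs were left out, and the macrophage-like difference of -1.38 became -3.16 at the finer clustering resolution and -2.91 at the lower doublet score.

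NK/ILC1-like cells made up 2.19% (1.92% to 2.48%) of the isotype control library and 3.43% (3.12% to 3.77%) of the anti-NKp46 library, and sub-clusters scored as NK rather than ILC1 held 73.9% and 76.4% of them. The sub-cluster scored as ILC1, of 61 and 99 cells, carried Trac at 0.25 of the T-like level. This was under the cut of 0.4 chosen after seeing the data, but above the 0 to 0.107 of the sub-clusters scored as NK. A sub-cluster of 4 and 3 NK/ILC1-like cells was set apart from the other sub-clusters by the macrophage and antigen presentation genes C1qa, C1qb, Lyz2 and Cd74, while Prf1, Klra4 and Gzma led it against all other cells. The sort can set the share of NK/ILC1-like cells. For the control, the label describes all CD45+ cells together with lineage-negative NK1.1+ cells reached by the intravenous CD45.2 antibody, whereas the cell type label of the other library names only lineage-negative NKp46+ NK1.1+ cells outside the vessels and so conflicts with that library's title. Counted without NK/ILC1-like cells, the monocyte-like difference was -9.04 points, the B-like difference 7.47 points and the T-like difference 6.81 points.

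Within the T lineage the subsets went apart. CD4 T-like cells made up 8.64% (8.12% to 9.19%) of the isotype control cells and 14.0% (13.4% to 14.7%) of the anti-NKp46 cells, and CD8 T-like cells 11.3% (10.7% to 11.9%) and 16.7% (16.0% to 17.3%). Much of this lay in 2 clusters led by Lef1, Tcf7 and Ccr7, genes of naive and recirculating T cells. Their part of the T-like cells was 10.3% against 25.4% for cluster 3 (CD4) and 8.12% against 18.0% for cluster 0 (CD8). Within their subsets cluster 3 held 37.7% against 68.6% of CD4 T-like cells and cluster 0 22.8% against 40.8% of CD8 T-like cells. Regulatory T-like cells were lower with the blocking antibody, 9.28% (8.73% to 9.84%) against 6.79% (6.35% to 7.25%). These subset shares varied with the settings. The CD4 difference of 5.39 points was 3.29 with no cell filter and 3.43 with the stricter one. The CD8 difference, also 5.39, was 1.23 at the coarser resolution. The regulatory difference of -2.48 was -0.339 at the finer resolution and -4.78 with each library clustered alone. At the finer resolution the regulatory class held only 3.60% and 3.26% of cells, and the CD4 class 14.7% and 18.2%. Many cells named regulatory in the main setting thus took another name there. Gamma-delta T-like cells expressing Il17a, the gene of a cytokine that recruits neutrophils, made up 2.5% (2.21% to 2.81%) against 0.368% (0.268% to 0.492%), a 6.79-fold lower share. At the coarser resolution their shares were closer, 2.47% against 0.932%. Type 2 conventional dendritic cells (cDC2) were 6.05-fold lower, 2.72% (2.42% to 3.05%) against 0.450% (0.339% to 0.585%). This fold varied with the settings, as the cDC2 shares were 2.15% and 0.109% at the doublet score of 0.10. Plasmacytoid dendritic cells, a main source of type I interferon, were 2.20-fold lower, 1.48% (1.26% to 1.72%) against 0.670% (0.533% to 0.831%). Type 1 conventional dendritic cells (cDC1) came to 1.64% (1.40% to 1.90%) and 1.31% (1.11% to 1.53%).

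**Figure D1:**
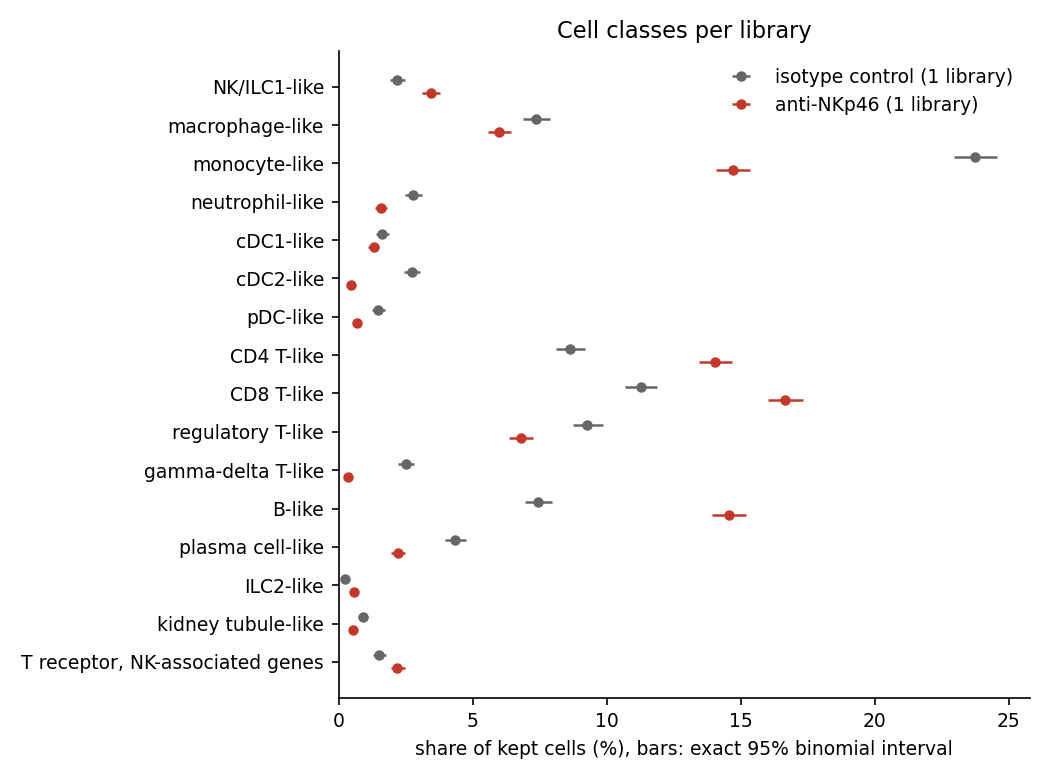
Share of kept cells (%, horizontal axis, starting at 0) of each marker-named class in the isotype control library (grey) and the anti-NKp46 library (red), with bars for the exact 95% binomial interval. Monocyte-like cells stand at 23.7% against 14.7% and B-like cells at 7.44% against 14.6%.

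Cells outside the named classes differed as well, and some rules that left them unnamed were set after the data had been seen. Clusters that carried markers of 2 lineages held 8.78% of the isotype control cells and 11.1% of the anti-NKp46 cells. Among them, cluster 4, led by Ccl12, Apoe and C1qa, matched macrophages best but carried T cell markers, and held 447 and 386 cells. Cluster 9, led by Hist1h1b, Mki67 and Birc5, carried markers of T cells and of monocytes or macrophages, and held 180 and 58 cells. The share and expression values of macrophage-like cells leave out both. Other mixed clusters were larger in the anti-NKp46 library. Cluster 24, led by Fcgr4, Adamdec1 and Fabp4, carried markers of T cells and of monocytes or macrophages, and held 253 and 661 cells. Cluster 28 matched B cells best but carried monocyte or macrophage markers, and held 11 and 224 cells. The monocyte-like and B-like values leave out these cells. Clusters 19 and 27 were small, with 40 and 0 cells and 8 and 28 cells. Clusters with few UMIs held 3.15% and 2.07%. Cells with T cell receptor transcripts and NK-associated genes, kept apart from NK/ILC1-like cells, held 1.52% (1.30% to 1.78%) and 2.19% (1.94% to 2.47%). A cluster led by Fcrl5, Adamdec1, Itgad and Fcgr4, with too few markers for a name, held 2 cells of the isotype control library and 94 cells of the anti-NKp46 library, which is 0.0187% and 0.768%. Being almost all from 1 library, it is not compared further.

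The second question was what the cells that carry NKp46 expressed, and the target gene came first. In NK/ILC1-like cells Ncr1 stood at 2151 counts per 1000000 UMIs of the class (CPM; 2049 to 2256) in the isotype control library and 2144 CPM (2052 to 2238) in the anti-NKp46 library. Its log2 ratio of -0.0048 (-0.099 to 0.089) was -0.14 with each library clustered alone and -0.10 with sub-clusters given the same weights. Xcl1, the chemokine that attracts cDC1, was 2.66-fold lower (2.35 to 3.01) in the anti-NKp46 library, at 1041 against 391.8 CPM, with a UMI in 88 of 234 and 91 of 420 cells, and its log2 ratio of -1.41 was -0.78 with sub-clusters given the same weights. Ccl4, a chemokine released on activation of NK cells, was 1.71-fold lower (1.62 to 1.80), at 4526 against 2650 CPM, with 391 of its 3510 UMIs in 1 cell of the isotype control library, and Ccl3 was 1.26-fold lower (1.16 to 1.38). Ifng, the gene of interferon gamma, showed no difference beyond counting error, at 181 CPM (152 to 213) and 204 CPM (177 to 235), and the same held for Tnf, at 51.6 and 48.7 CPM. The sums rest on 234 and 420 cells with medians of 3066 and 2218 UMIs.

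The cytotoxic effector genes differed little. Gzma was 1.15-fold lower (1.11 to 1.19), Gzmb 1.2-fold lower (1.13 to 1.28) and Prf1, which encodes the pore-forming protein perforin, 1.09-fold lower (1.02 to 1.16) in the anti-NKp46 library, whereas Ccl5 was 1.17-fold higher (1.14 to 1.19). Csf2, the gene of GM-CSF, was 4.48-fold lower (1.60 to 15.4), but 16 of its 18 UMIs in the isotype control library lay in 1 cell, and with each library clustered alone its log2 ratio was 0.64. The granzyme gene Gzmc likewise had 48 of 66 UMIs in 1 cell of the isotype control library, against 2 UMIs in the other. A UMI of Ncr1 was found in 92.7% (88.6% to 95.7%) and 92.1% (89.1% to 94.5%) of NK/ILC1-like cells, and after thinning each cell to 1000 UMIs in 81.0% and 79.6%. A UMI of Ifng was found in 34.2% and 30.2% unthinned and in 16.4% and 18.0% thinned. Thinning left out 2 and 14 shallower cells. In B-like cells, with median depths of 2716 and 2391 UMIs, Ncr1 was seen in 0.252% and 0.112% and Ifng in 1.64% and 1.12% unthinned, and in 0.264%, 0.116%, 0.792% and 0.407% thinned.

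**Figure D2:**
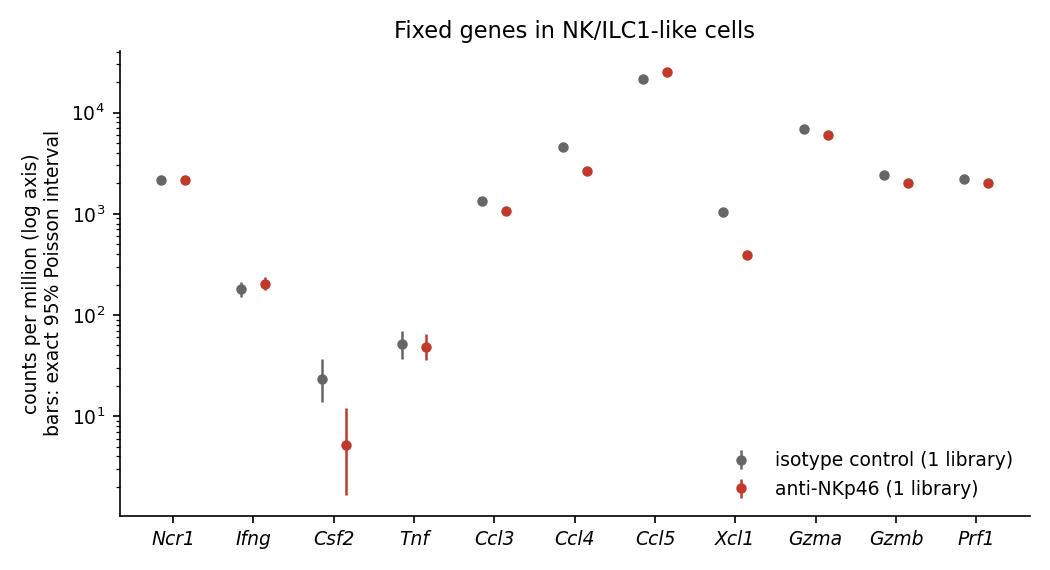
CPM (vertical log axis) of the 11 fixed genes in NK/ILC1-like cells of the isotype control library (grey) and the anti-NKp46 library (red), with exact 95% Poisson intervals. Ncr1 stands at 2151 and 2144 CPM, while Xcl1 stands at 1041 and 391.8.

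Genes of immune receptor activation, which are switched on downstream of activating receptors, were lower in NK/ILC1-like cells of the anti-NKp46 library. Of 20 measured members, 7 were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median log2 ratio of -0.42 that lay below all 10000 expression-matched random lists. Tnfrsf9, the costimulatory receptor 4-1BB, was 2.42-fold lower (1.89 to 3.12), or 1.46-fold (1.08 to 1.99) without the sub-cluster of 14 and 4 cells that it leads. Lower as well were Nr4a1, an early gene of receptor signalling, 2.19-fold lower (1.64 to 2.95), Nr4a3 1.88-fold lower (1.26 to 2.83) and Relb, an NF-kappaB subunit, 1.78-fold lower (1.22 to 2.61). NK cytokines and chemokines had a median of -0.45, with 6 of 14 members at least 1.5-fold lower and 0 higher, again below all random lists, although this median was -0.25 when sub-clusters were given the same weights and -0.016 when each library was clustered alone. Among them Ccl9 was 2.07-fold lower (1.37 to 3.17), while Ccl1, 3.01-fold lower (1.73 to 5.44), was seen in only 4 and 3 cells. Crtam, an adhesion receptor that appears after activation, was 2.35-fold lower (1.53 to 3.64), while the activating receptors and adaptors as a list had a median of -0.048 (percentile 12.7) and the inhibitory receptors -0.049 (percentile 19.8).

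Genes of NK maturation were higher, with a median of 0.20 (percentile 99.9). Cx3cr1, a receptor of circulating mature NK cells, was 1.84-fold higher (1.41 to 2.41) and S1pr5, which drives exit from tissue, 1.66-fold higher (1.39 to 1.99). The immaturity list had a median of -0.28 (percentile 0.03) and the ILC1 and tissue residency list one of -0.18 (percentile 0.98). With each library clustered alone these 3 medians were 0.044, 0.28 and -0.011. Interferon response genes were higher, with a median of 0.31 (percentile 99.98), 8 of 33 members at least 1.5-fold higher and 1 lower; Isg15 was 2.19-fold higher (1.36 to 3.61), Bst2 2.18-fold higher (1.52 to 3.19) and Xaf1 2.13-fold higher (1.25 to 3.76). The interferon gamma response list stood at 0.11 (percentile 85.7), the cytotoxicity list at 0.019 (percentile 62.8) and proliferation at 0.072 (percentile 68.8). Genes of the secretory pathway and unfolded protein response had a median of 0.24 (percentile 99.99), with Dnajb9 1.74-fold higher (1.06 to 2.91) and Sdf2l1 1.53-fold higher (1.2 to 1.94).

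The MHC class II list had a median of -0.99 in NK/ILC1-like cells, with Cd74 at 468 against 154 CPM and 113 of its 363 UMIs in 1 cell of the isotype control library. Markers of B cells stood at 72.2 CPM (54.5 to 93.8) against 9.33 CPM (4.27 to 17.7) and macrophage markers at 155 CPM (128 to 185) against 47.7 CPM (34.9 to 63.6) in the same cells, and the list's median was -0.33 without the sub-cluster of 4 and 3 cells led by macrophage genes and 0.60 with doublets kept. Among all genes that met the rule for naming, the highest ratios were those of Arl4d, 2.53-fold higher (1.62 to 4.06), Ap1s1, 2.35-fold higher (1.5 to 3.79), and As3mt, 2.27-fold higher (1.46 to 3.63). Gclm, a subunit of the enzyme that starts glutathione synthesis, was 2.03-fold higher (1.60 to 2.60) and Fkbp4, a co-chaperone of HSP90, 1.87-fold higher (1.42 to 2.48). Among the lowest, Serpina3g was 2.16-fold lower (1.64 to 2.86) and Traf1, a signalling adaptor of 4-1BB, 1.87-fold lower (1.37 to 2.55).

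**Figure D3:**
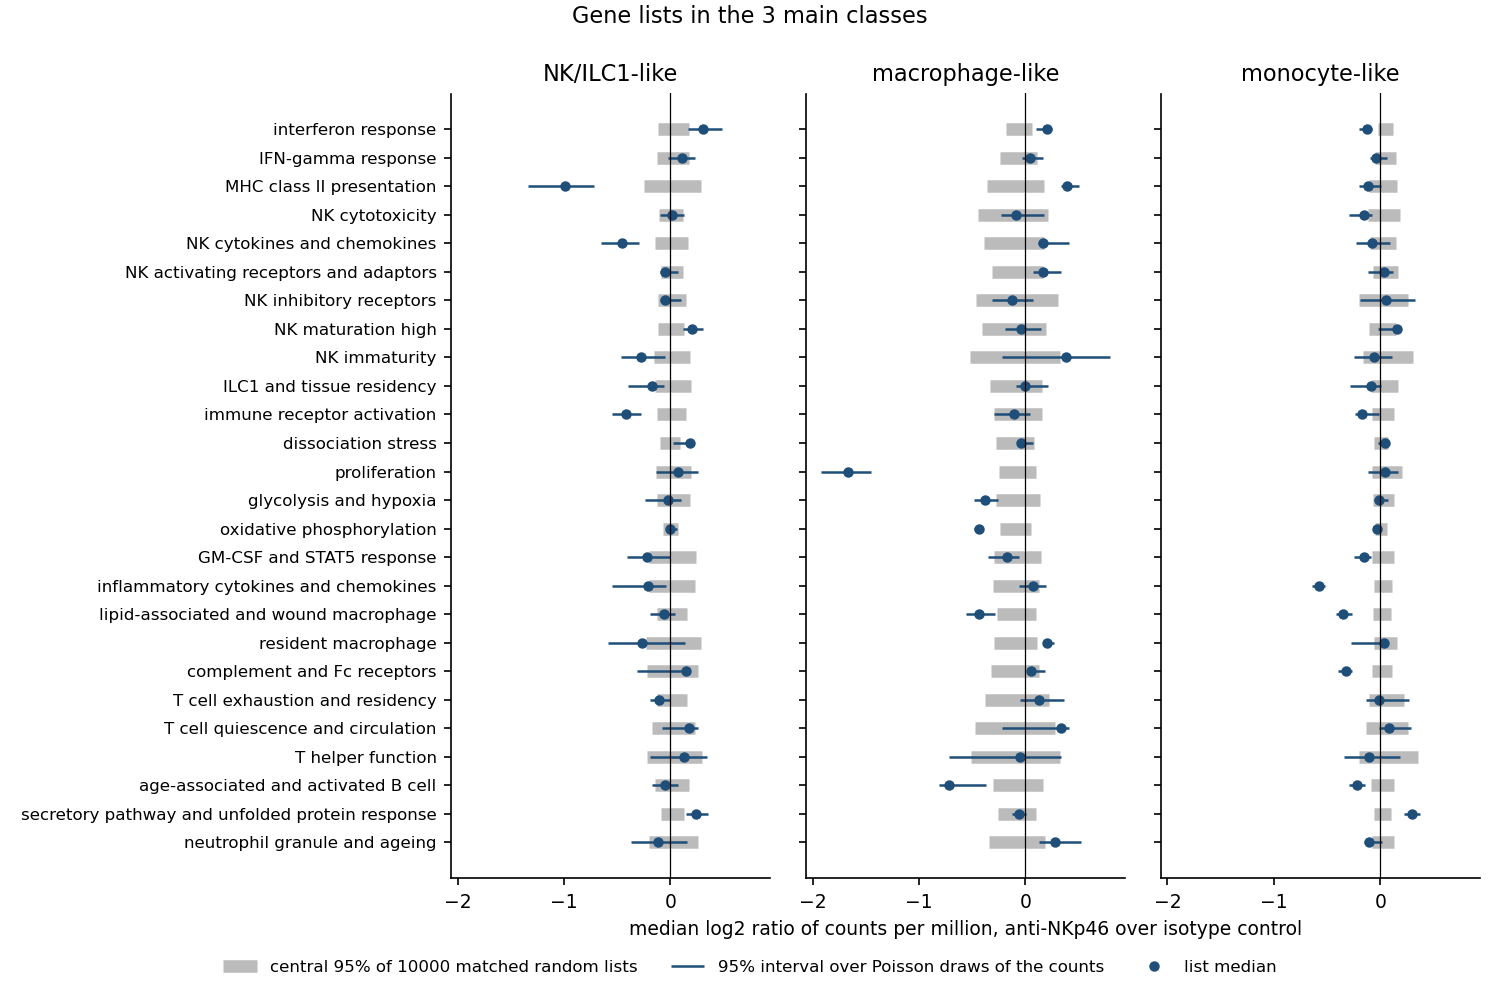
Median log2 ratio of CPM (anti-NKp46 over isotype control, horizontal axis) of 26 gene lists in NK/ILC1-like, macrophage-like and monocyte-like cells, with blue lines for the 95% interval over Poisson draws of the counts and grey bars for the central 95% of 10000 expression-matched random lists. Proliferation in macrophage-like cells lies at -1.67, and the inflammatory list in monocyte-like cells at -0.57.

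Macrophage-like cells, 1 cluster of 789 and 734 cells with medians of 4045 and 2378 UMIs, differed most in proliferation genes. All 38 measured members were lower in the anti-NKp46 library, 34 of them at least 1.5-fold, with a median log2 ratio of -1.67 below all random lists. Mki67, a marker of cycling cells, was 5.71-fold lower (3.69 to 9.29), at 66.8 CPM (58.6 to 75.8) against 11.7 CPM (7.33 to 17.7). Stmn1 was 2.82-fold lower (2.21 to 3.65) and Mcm5, a subunit of the replicative helicase, 2.87-fold lower (2.03 to 4.15). The median was -1.09 under the stricter cell filter and -0.52 with each library clustered alone. These values leave out the unnamed cluster 4, which matched macrophages best, and the unnamed cluster 9, which was led by proliferation genes.

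The inflammatory genes of macrophage-like cells went in both directions. Il1b, the gene of interleukin-1 beta, was 2.09-fold higher (1.96 to 2.23) with the blocking antibody, at 493 CPM (470 to 517) against 1033 CPM (987 to 1080). Ccl2, the main attractant of classical monocytes, was 2.30-fold lower (2.12 to 2.49), at 885 CPM (854 to 916) against 385 CPM (358 to 414), and Ccl12, another ligand of the same receptor, 2.18-fold lower (2.00 to 2.38). Cxcl2, which attracts neutrophils, was 2.98-fold lower (2.65 to 3.37). The list of inflammatory cytokines and chemokines as a whole had a median of 0.072 (percentile 92.2), with 6 of 24 members at least 1.5-fold higher and 5 lower. Spp1, the gene of osteopontin, was 5.55-fold lower (4.32 to 7.24), at 198 against 35.6 CPM, with a UMI in 215 and 37 cells; it is also abundant in kidney tubule cells and reached 7.76 and 1.74 CPM in B-like cells. Tnf was level, at 145 and 156 CPM. The GM-CSF receptor gene Csf2ra was 1.25-fold lower (1.15 to 1.36), and Csf2rb, at 94.8 and 78.7 CPM, did not differ beyond counting error. Cxcl9 was 1.31-fold higher (1.06 to 1.61), but 69 of its 152 UMIs in the anti-NKp46 library were in 1 cell and its log2 ratio was -0.27 in thinned cells, and Cxcl10 was level, at 59.0 and 55.8 CPM.

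Genes of antigen presentation and of resident macrophages were higher. The MHC class II list had a median of 0.39 (percentile 99.96), with 14 of 15 members higher, among them Ciita, the master regulator of the pathway, 1.60-fold (1.36 to 1.88), and H2-Eb1 1.58-fold (1.56 to 1.61). The resident macrophage list had a median of 0.20 (percentile 99.8), with 18 of 23 members higher. Hpgd, which inactivates prostaglandins, was 5.17-fold higher (4.27 to 6.29), at 41.1 CPM (34.7 to 48.3) against 213 CPM (192 to 235). Cd81 was 1.79-fold higher (1.73 to 1.86) and Ms4a7 1.67-fold higher (1.59 to 1.76), whereas Pf4 was 1.83-fold lower (1.49 to 2.26). The list of lipid-associated and wound macrophages had a median of -0.43, below all random lists, with 12 of 26 members at least 1.5-fold lower. In it Anxa1 was 3.27-fold lower (2.17 to 5.11), while Igf1, a growth factor of tissue repair, was 4.04-fold higher (2.92 to 5.65). Markers of other cells were higher in the macrophage-like cells as well: those of B cells at 209 CPM (194 to 225) against 384 CPM (356 to 413), and those of kidney tubule at 118 CPM (107 to 129) against 571 CPM (538 to 607).

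Metabolic genes of macrophage-like cells were lower. Of 42 genes of oxidative phosphorylation, 41 were lower and 7 of them at least 1.5-fold, with a median of -0.43, and the glycolysis and hypoxia list had a median of -0.38 (percentile 0.11), with the glycolytic enzyme gene Eno1 2.63-fold lower (1.86 to 3.81). Interferon response genes were higher, with a median of 0.20 above all random lists and 8 of 52 members at least 1.5-fold higher and 0 lower; Oasl1 was 2.00-fold higher (1.5 to 2.67). The interferon gamma response list stood at 0.043 (percentile 89.2), the GM-CSF and STAT5 response list at -0.18 (percentile 16.8) and the secretory list at -0.055 (percentile 56.2). Among all genes, the highest ratio, in cells whose kidney tubule markers were also higher, was that of Slc6a12, an osmolyte transporter that cells induce in hypertonic surroundings, 8.29-fold higher (5.33 to 13.4). It was followed by Hpgd, Slco4a1 (4.93-fold, 3.58 to 6.88) and Fcrl5 (4.39-fold, 3.23 to 6.04). The lowest were Anxa3, 5.79-fold lower (3.52 to 10.1), Mki67, Clec4n (3.36-fold, 2.62 to 4.36), Tmem119 (3.32-fold, 2.44 to 4.60) and the scavenger receptor gene Msr1 (3.27-fold, 2.43 to 4.47).

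Monocyte-like cells, 2538 and 1799 with medians of 3627 and 2690 UMIs, were spread differently over their clusters. Cluster 10, led by Acod1, Clec4e and Il10, held 55.7% of them in the isotype control library and 42.5% in the anti-NKp46 library, cluster 8, led by the patrolling monocyte genes Ace and Treml4, held 18.1% and 44.2%, and cluster 16, led by Fn1 and Vcan, held 26.2% and 13.2%. Inflammatory cytokines and chemokines were lower as a list in the anti-NKp46 library. Of 26 measured members, 13 were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median of -0.57 below all random lists. Giving the clusters the same weights in both libraries left a median of -0.38. Ccl2 was 3.50-fold lower (3.12 to 3.93), at 189 CPM (182 to 197) against 54.1 CPM (48.6 to 60.1); within clusters it was 2.76-fold lower (2.11 to 3.64) in cluster 8, 3.03-fold lower (2.63 to 3.51) in cluster 16 and 1.27-fold lower (0.920 to 1.78) in cluster 10. Ccl7 was 6.74-fold lower (4.88 to 9.56), with a UMI in 44 and 7 cells. Cxcl10, a target of interferons, was 1.70-fold lower (1.35 to 2.15), and Cxcl9, with 114 of its 139 UMIs in 1 cell of the anti-NKp46 library, is not read.

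The 10 lowest ratios in monocyte-like cells included those of Il10, Acod1, Hp and Sod2. Il10, the gene of an anti-inflammatory cytokine, was 2.36-fold lower (2.09 to 2.66), Acod1, which makes itaconate, 2.5-fold lower (2.22 to 2.83), the haptoglobin gene Hp 2.46-fold lower (2.36 to 2.56) and Sod2, the mitochondrial superoxide dismutase, 2.09-fold lower (1.99 to 2.20). Within cluster 10 alone Il10 was 2.32-fold lower (2.02 to 2.68) and Hp 2.75-fold lower (2.59 to 2.93). In clusters 8 and 16 Il10 was 1.33-fold (0.963 to 1.82) and 1.70-fold (0.983 to 3.11) lower, not beyond counting error. Acod1 was 1.12-fold lower (0.682 to 1.82) in cluster 8 and 1.76-fold lower (1.16 to 2.73) in cluster 16. Hp was lower in both, 2.15-fold (1.97 to 2.35) and 1.59-fold (1.48 to 1.71). Areg, a growth factor for epithelium, was 3.48-fold lower (3.02 to 4.02), and Il1b 1.24-fold lower (1.2 to 1.28), while Tnf was 1.2-fold higher (1.11 to 1.29). Csf2rb, which encodes the signalling chain of the GM-CSF receptor, was 1.47-fold lower (1.37 to 1.57) and Csf2ra 1.13-fold lower (1.08 to 1.19), and the GM-CSF and STAT5 response list had a median of -0.15 (percentile 0.05). Fcgr4, an activating receptor for IgG, was 2.29-fold higher (2.18 to 2.42), at 223 CPM (214 to 231) against 511 CPM (493 to 528), and was higher in each of the 3 clusters. The complement and Fc receptor list as a whole had a median of -0.32, which was 0.098 with equal cluster weights, and the lipid-associated list one of -0.35, which was -0.025 with them.

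Interferon response genes, higher in NK/ILC1-like and macrophage-like cells, were slightly lower in monocyte-like cells, with a median of -0.13 below all random lists. With equal cluster weights the median was -0.013. The interferon gamma response list stood at -0.035 (percentile 5.26) and MHC class II at -0.11 (percentile 2.06). Genes of the secretory pathway and unfolded protein response had a median of 0.30 above all random lists, with 25 of 26 members higher, among them Creld2, 1.89-fold (1.64 to 2.19), and Sdf2l1, 1.87-fold (1.71 to 2.04). The highest ratios of all were led by the heat-shock gene Hsph1, 2.80-fold higher (2.52 to 3.11), followed by Fcgr4, Stip1 (2.17-fold, 2.00 to 2.37) and Hfe (2.07-fold, 1.94 to 2.20). Spp1 was 1.99-fold lower (1.64 to 2.42) and Mmp14, a membrane-bound matrix protease, 2.80-fold lower (2.47 to 3.18).

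In the other classes the interferon response list was higher in the anti-NKp46 library throughout. Its median was 0.38 in B-like cells, 0.56 in plasma cells and 0.34 in T-like cells, each above all random lists, 0.24 in cDC1 (percentile 99.99) and 0.20 in neutrophil-like cells (percentile 98.8). In the cDC1, markers of CD8 T cells stood at 604 CPM against 1063 CPM, of CD4 T cells at 349.9 against 573, of B cells at 109 against 187 and of migratory dendritic cells at 264 against 561. The labels name poly(I:C), an inducer of these genes, for the isotype control mice alone. In plasma cells the interferon gamma response list was at 0.81. Of the interferon response list, Ly6a was 5.03-fold higher (4.82 to 5.26) in plasma cells and Stat1, the signal transducer of interferons, 3.26-fold higher (2.85 to 3.74). Markers of other cell types were higher in the same cells, those of CD8 T cells at 511 CPM against 916 CPM, of monocytes at 693 against 1311 and of migratory dendritic cells at 279 against 611. Plasma cells were deep, at medians of 15468 and 11464 UMIs. B4galt5 was 15.5-fold higher (10.4 to 23.9) in them, but 164 of its 188 UMIs in the anti-NKp46 library were in 1 cell. The secretory list had a median of 0.20 in plasma cells (percentile 90.9). Proliferation genes were lower in plasma cells (-0.69), cDC1 (-0.99) and CD8 T-like cells (-0.74), below all random lists in each, and the last was -0.36 with the 2 clusters of CD8 T-like cells given the same weights. In B-like cells they were higher (0.63, above all random lists), with Mki67 2.21-fold higher (1.69 to 2.93), and the age-associated and activated B cell list had a median of 0.13 (percentile 98.1), which was 0.21 with equal cluster weights.

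In T-like cells, whose subsets were mixed differently in the 2 libraries, Il17a was 15.1-fold lower (11.1 to 20.9), at 69.1 against 4.58 CPM. The share of gamma-delta cells was 6.79-fold lower in the main setting, and 2.47% against 0.932% at the coarser resolution. Sell and Ccr7, homing receptors for lymph nodes, were 2.36-fold (2.18 to 2.55) and 2.29-fold higher (2.14 to 2.45). The quiescence and circulation list had a median of 0.41 above all random lists in T-like cells, 0.44 in CD8 T-like cells and 0.037 (percentile 84.7) in CD4 T-like cells. With clusters given the same weights in both libraries these medians were -0.085, -0.098 and -0.043. The exhaustion and residency list stood at -0.035 (percentile 64.8) in T-like cells, and at 0.23 with equal weights. The T helper list was -0.57 in CD4 T-like cells, below all random lists, but 0.19 with equal weights, and 0.22 (percentile 99.8) in regulatory T-like cells. The last form 1 cluster in the main setting, so no equal weights could be given. Its leading genes included Cd40lg, Pdcd1 and Icos beside Ikzf2 and Ctla4, and the class held only 3.60% and 3.26% of cells at the finer resolution. A different mix of cells inside this cluster was therefore not taken out. In neutrophil-like cells the granule and ageing list had a median of -0.39 below all random lists. Outside that list, the decoy receptor gene Il1r2 was 3.33-fold lower (2.79 to 4.01) in neutrophil-like cells, while Wfdc17 was 3.26-fold higher (2.98 to 3.57). Neutrophil markers as a set were higher in the same cells, at 57211 against 83546 CPM, as were those of B cells, at 90.02 CPM (68.7 to 116) against 572 CPM (509.7 to 639.6).

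A group of temperature-dependent genes differed between the libraries in every class examined. The median log2 ratio of 10 heat-shock genes of the dissociation stress list lay between 0.40 in NK/ILC1-like cells and 1.03 in neutrophil-like cells over the 11 named classes with at least 50 cells in each library. Rbm3 and Cirbp, which cells make in the cold, had log2 ratios between -1.61 and -0.56 and between -1.53 and -0.25. In B-like cells Rbm3 was 2.03-fold lower (1.91 to 2.16), at 836 against 412 CPM, and Hsph1 2.19-fold higher (1.82 to 2.67), at 52.0 against 114 CPM. The dissociation stress list as a whole had medians of 0.18 (percentile 100), -0.040 (percentile 73.4) and 0.042 (percentile 86.9) in NK/ILC1-like, macrophage-like and monocyte-like cells, and the first of these was -0.0033 in cells thinned to 1000 UMIs. Among its other members Socs3, a feedback inhibitor of cytokine signalling, was 2.06-fold lower (1.48 to 2.88) in NK/ILC1-like cells.

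**Figure D4:**
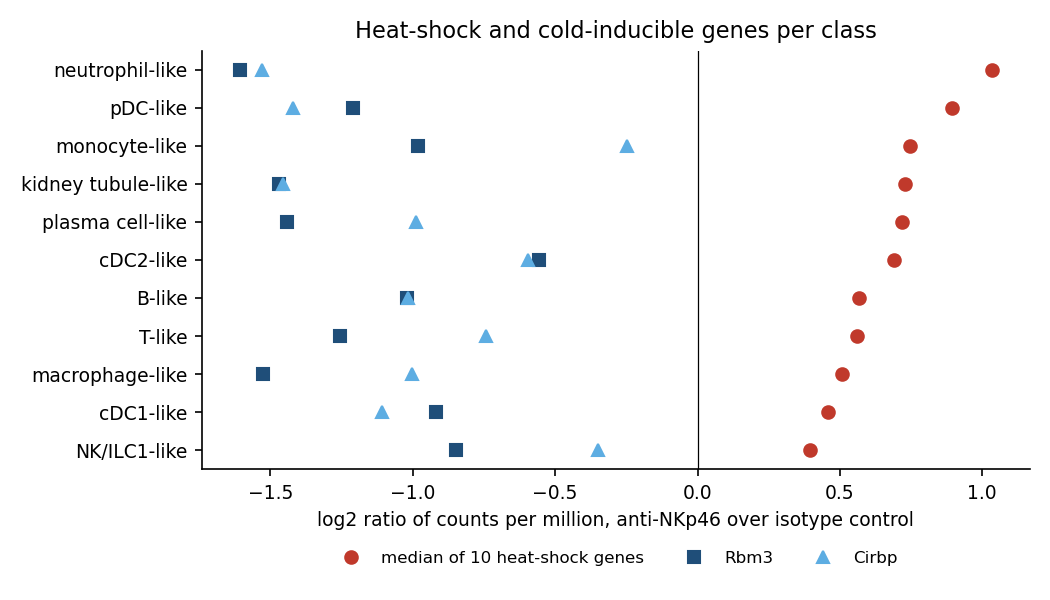
Log2 ratio of CPM (anti-NKp46 over isotype control, horizontal axis) per named class with at least 50 cells in each library, as the median of 10 heat-shock genes (red circles) and the values of Rbm3 (dark blue squares) and Cirbp (light blue triangles). The heat-shock medians lie between 0.40 and 1.03, and all Rbm3 and Cirbp values lie below 0.

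The genes at the centre of these comparisons are protein-coding and lie as follows in the mouse build GRCm38. Ncr1 (ENSMUSG00000062524) lies on chromosome 7 from 4337724 to 4345164, Xcl1 (ENSMUSG00000026573) on chromosome 1 from 164931644 to 164935527, and Ccl4 (ENSMUSG00000018930) and Ccl2 (ENSMUSG00000035385) on chromosome 11 from 83662584 to 83664683 and from 82035571 to 82037453. Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139, Hpgd (ENSMUSG00000031613) on chromosome 8 from 56294585 to 56321043, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050, and Fcgr4 (ENSMUSG00000059089) on chromosome 1 from 171018920 to 171029761. Hsph1 (ENSMUSG00000029657) lies on chromosome 5 from 149614287 to 149636376, Rbm3 (ENSMUSG00000031167) on chromosome X from 8138975 to 8145880, and Cirbp (ENSMUSG00000045193) on chromosome 10 from 80165985 to 80172786.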

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

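The doublet score of 0.10, all settings for the shares of T subsets, dendritic cells, group 2 innate lymphoid cells and tubule cells, the removal of cells with markers of another lineage, the removal of a sub-cluster led by macrophage genes and the equal cluster weights were chosen after the results were seen. Over the alternatives run, 115 of 135 differences in share of 16 classes stayed inside the main interval and all 135 kept their sign; gene ratios were run in the 3 main classes, and lists also, under equal weights alone, in B-like and T-like cells and the CD4 and CD8 subsets. Of 308 log2 ratios of fixed genes, 250 stayed inside it and 293 kept their sign, and of 1134 list medians 951 and 961. No paired analysis was possible because each group is 1 pooled library. The neutrophil-like share had no value under the stricter filter, at resolution 0.6 or with all variable genes, where no such class was found in at least 1 library, and the same held for cDC2 at resolution 0.6 and with each library alone, gamma-delta T-like cells with each library alone, regulatory T-like cells with no filter and at resolution 0.6, and group 2 innate lymphoid cells at resolution 0.6. Depth limits genes with few UMIs in NK/ILC1-like cells.

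Of the shares, the T-like difference was 1.36 points with the stricter filter and 7.49 at doublet score 0.10. The macrophage-like difference was -3.16 at resolution 2.0 and -2.91 at doublet score 0.10, the monocyte-like difference -4.96 at resolution 0.6, and the B-like difference 6.02 with doublets kept; the cause was not tested. With each library clustered alone, log2 ratios in NK/ILC1-like cells were -0.14 for Ncr1, 0.64 for Csf2, -0.016 for the cytokine list and 0.28 for the immaturity list. With equal cluster weights Ncr1 was -0.10 and the cytokine list -0.25, and with no minimum of UMIs the cytokine list was -0.25. The dissociation stress list was -0.0033 in thinned cells and MHC class II 0.60 with doublets kept. In macrophage-like cells Cxcl9 was -0.046 as a mean of per-cell CPM, -0.27 in thinned cells and -0.092 at doublet score 0.10, where the activating receptor list was -0.023. In monocyte-like cells Cxcl9 was -0.44 with each library alone and -3.07 at doublet score 0.10, and the complement list 0.14 at that score and 0.098 with equal weights. There the interferon list was -0.071 as a mean of per-cell CPM and -0.013 with equal weights, and the interferon gamma list 0.076 as a mean of per-cell CPM and -0.10 at doublet score 0.10. With equal weights in T-like cells the glycolysis list was 0.060, the quiescence list -0.085, the T helper list 0.16 and the activated B cell list 0.033, in CD4 T-like cells the T helper list 0.19, and in CD8 T-like cells the NK maturation list 0.037, the lipid-associated list 0.013 and the quiescence list -0.098. The cause was not tested for any of these, except that equal weights take out the difference in cluster mix.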

Other observations

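The equal cluster weights, the tests over other classes, those of the heat-shock and cold-inducible genes and that of the neutrophil-like share were chosen only after the result was seen, as was the use of the thinned cells and of the stricter filter, both planned as alternatives, to weigh these patterns. In regulatory T-like cells the inflammatory cytokine list had a median of 0.33 (percentile 97.8) and the exhaustion and residency list one of 0.20 (percentile 99.2). Markers of B cells stood at 23.9 against 56.1 CPM in these regulatory T-like cells and erythroid markers at 7.51 against 218.5 CPM. Their macrophage markers went the other way, at 579 against 353 CPM. The GM-CSF and STAT5 response list was lower in CD4 T-like cells (-0.80) and CD8 T-like cells (-0.62), below all random lists in both, and was -0.23 and -0.44 with the clusters of each subset given the same weights. Macrophage markers were lower in the same cells, at 121 against 79.5 CPM in CD4 T-like cells and 278 against 46.1 CPM in CD8 T-like cells, as was the complement and Fc receptor list, at -0.69 and -1.45. In cDC1 Rrm2, a subunit of ribonucleotide reductase, was 7.46-fold lower (4.03 to 15.3), with a UMI in 23 and 7 cells, and Mcm3 3.22-fold lower (2.28 to 4.67). Group 2 innate lymphoid cells made up 0.224% (0.144% to 0.334%) of the isotype control library and 0.589% (0.461% to 0.741%) of the anti-NKp46 library, and kidney tubule cells 0.898% (0.728% to 1.1%) and 0.540% (0.418% to 0.686%), with differences of 0.364 and -0.358 points that were 0.844 with each library clustered alone and -0.125 under the stricter filter.

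Genes of immune receptor activation were lower in NK/ILC1-like cells of the anti-NKp46 library. Without the sub-cluster led by Tnfrsf9 and Crtam, of 14 and 4 cells, the median was -0.36. This argues against the few activated cells of that sub-cluster as the whole cause. With cells thinned to 1000 UMIs the median was -0.38, but random thinning leaves ratios of summed counts nearly unchanged by design. The cells were also not clustered again after thinning, so this value decides nothing about depth. The median over 9 other classes was -0.11, which argues against a shift of the same size in every class, although CD4 T-like cells stood at -0.42 (-0.032 with equal cluster weights), neutrophil-like cells at -0.27 and B-like cells at -0.26. An effect of the blocking antibody, a difference between the 2 pools of mice, the conflicting gate labels and poly(I:C) all remain open and untested. Depth remains open as well.

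Heat-shock genes were higher and Rbm3 and Cirbp lower in the anti-NKp46 library. The signs were the same in all 11 classes examined, but the genes were chosen from these values, so this count cannot support a difference in temperature or handling between the libraries. The heat-shock median of NK/ILC1-like cells, 0.40, was the lowest of these classes, which argues against an effect specific to cells that carry NKp46. A difference in handling and an effect of the treatment on the whole animal both remain open, and the second was not tested.

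T-like and B-like cells had larger shares in the anti-NKp46 library. Under the stricter filter the T-like difference was 1.36 points, so its size depended on the cells this filter left out. Of T-like cells, 8.15% and 26.6% had under 800 genes, with medians of 1209 and 922 genes. A fixed cut thus takes out more T-like cells in the shallower anti-NKp46 library, whatever they are. The smaller difference therefore does not decide whether shallow cells account for the larger T-like share. The B-like difference was 7.72 points under the same filter, which argues against shallow cells as the explanation for B-like cells. The neutrophil-like share differed by -1.22 points, the opposite of what more whole blood would give. It does not decide the question, as it counts neutrophils of blood and tissue together and the gradient can hold back granulocytes unevenly. Cluster 8, led by patrolling monocyte genes, was higher, at 4.29% against 6.51% of kept cells. Haemoglobin (93.9 against 70.3 CPM) and platelet markers (22.1 against 7.73 CPM) decide little. The gradient removes red cells, and macrophage-like cells carried platelet markers at 119.7 against 67.0 CPM. More blood or vessel cells thus remains open. Lymphoid tissue in the digest, the conflicting gate labels and an effect of the antibody remain open and untested.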
